A study of Homo sapiens with 2 samples.

How the data were processed

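The series describes 1 culture of the human embryonic stem cell line HES2 that had been differentiated towards sinoatrial node-like pacemaker cells, abbreviated SANLPC in the labels. The 2 samples of the series are 2 libraries of the same cells, 1 of polyadenylated RNA and 1 of the barcode tags carried by an antibody against human CD34. This pairing of transcripts and antibody tags per cell is called CITE-seq. Per the labels' protocols, cells were dissociated, stained with the barcoded antibody, sorted as live singlets with the dye DAPI and built into droplet libraries with a 10x Genomics 3' version 3 kit. The sort did not select on CD34. The deposited matrix held whole-number counts of unique molecular identifiers (UMIs) for 36601 genes and for the antibody tag in 14829 barcodes. Per the file headers and the submitters' processing notes, the counts were made with Cell Ranger 6.1.2, and the notes name the genome build GRCh38. No normalization, cell filter beyond the listed barcodes or cell annotation was recorded in the sources used here. Each transcript was counted near its 3' end, so the counts carry no information on isoforms.

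The barcodes together held 239181462 RNA UMIs and 2773855 antibody-tag UMIs, and the shallowest held 500 RNA UMIs. Barcodes with under 1000 detected genes (1975) or with over 25% mitochondrial UMIs (1207) were left out, which removed 2710 in all and left 12119. Doublets, droplets that held more than 1 cell, were called with Scrublet as implemented in scanpy 1.11.5, and the 1435 called (11.8% of barcodes, score over 0.109) were removed. The 10684 kept cells had a median of 16504.5 RNA UMIs, with 5th and 95th percentiles of 4320.45 and 32277.85, a median of 4533 genes and a median mitochondrial share of 8.15%. Their antibody-tag UMIs had a median of 51 and quartiles of 34 and 100.

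Cells were clustered on RNA alone. The 2000 most variable genes were taken, with CD34, mitochondrial and ribosomal protein genes left out, so that cluster and CD34 level were measured separately. Counts were scaled per cell and log-transformed, and 30 principal components, 15 nearest neighbours and Leiden clustering at resolution 1 gave 20 clusters. Clusters were named "X-like" from 14 marker lists fixed before the data were examined, as were 21 gene groups, the comparisons, the rule for named genes and most alternatives. The naming rule itself was set after the clusters, and the CD34 protein level of each, had been seen. A cluster was cardiomyocyte-like where its cardiomyocyte markers averaged over 8 on the log2 scale of CPM, counts scaled to a common total per library. It was called cycling where cell cycle markers averaged over 1 log2 unit above the median cluster. Each remaining cardiomyocyte-like cluster was scored by the mean log2 ratio of pacemaker and of working markers to the median cardiomyocyte-like cluster. The name pacemaker-like or working-like required a positive score above the other score and at least 3 markers at 50 CPM or more. It also required at least 1 of those markers, and no more of any other class, among the leading 10 genes against the other cardiomyocyte-like clusters. Other clusters were named where the markers of a class averaged at least 1 log2 unit above the median cluster and were among the leading genes. Clusters whose median depth lay under the median of all cells divided by 3 were left unnamed. All names are therefore rebuilt, and the labels give no cell type below the level of the culture.

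CD34 protein was taken as antibody-tag UMIs per cell as deposited. A background level was set after the data were seen, at the 99th percentile of the unnamed non-cardiomyocyte cells (163 antibody-tag UMIs). CD34-high and CD34-low cells were those at or above the 75th and at or below the 25th percentile of antibody-tag UMIs, taken over all kept cells, over cardiomyocyte-like cells or over pacemaker-like cells. These are ranges of a continuous measure, not cell types. Within 10% of the upper and lower limits lay 145 and 434 of the cardiomyocyte-like cells, and 108 and 132 of the pacemaker-like cells. For each gene, counts were summed over the cells of a range, scaled to CPM and compared as a ratio. Genes with at least 50 CPM in the higher range were measured. The rule for named genes took the 12 highest and 12 lowest ratios among them, leaving out CD34, mitochondrial and ribosomal protein genes, and members of the gene groups were also named, apart from some that are not reported here. Members of a group were counted as higher at a ratio of at least 1.25, lower at 0.8 or below, and between otherwise. A group's median log2 ratio was placed as a percentile among 10000 random lists of the same size, matched on mean expression in 20 bins, which describes these libraries only.

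Shares of cells with a UMI of a gene were computed after thinning each cell to 5000 RNA UMIs, with shallower cells left out. All cells come from 1 culture and cells are not replicates, so no p-value, standard error or number of changed genes was computed. Sums of counts have exact Poisson intervals and shares have exact binomial (Clopper-Pearson) intervals, both at 95%. These cover counting error only, not variation between cultures. A count of 0 was read as an upper limit of 3 counts. The ratio and list steps were tested on simulated counts for the cardiomyocyte-like ranges, with 200 of 3171 genes changed. The intervals held the true ratio for 95.5% of genes, a list of 10 genes raised 1.3-fold reached percentile 100, and of 100 unchanged lists 3 lay above and 1 below the central 95%. The simulated sums were Poisson counts without variation between cells. Coverage near 95% was therefore built in, and the test checks the computation, not coverage in these cells.

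Alternatives kept the called doublets, used a stricter cell filter (2000 RNA UMIs, 1000 genes and 15% mitochondrial UMIs), changed the clustering resolution to 0.5 or 2, divided antibody-tag UMIs by RNA UMIs, took the highest and lowest 10% or a split at the median, drew the groups within 10 bins of RNA UMIs, thinned to 2500 UMIs, left out cycling clusters or lowered the expression floor to 10 CPM. Further alternatives, added after the data were seen, drew the groups within each cluster or within bins of mitochondrial share, split cells at the background level or narrowed the pacemaker-like class. Gene positions are those of RefSeq on GRCh38. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.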

Results

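The data were collected from 1 differentiation of HES2, a human embryonic stem cell line, towards pacemaker cells of the sinoatrial node, the tissue that sets the heartbeat. CD34 is a surface sialomucin used to mark blood stem and progenitor cells and endothelium. Each cell was measured for its transcripts and for CD34 protein through a barcoded antibody. The title of the series concerns CD34 as a marker of human sinoatrial pacemaker cardiomyocytes, and the comparisons ask in which cells of this culture CD34 protein was found and which transcripts went with it. The RNA and antibody-tag libraries came from the same cells, so there is 1 culture and no replicate. All intervals of counts and shares are exact 95% intervals that cover counting error only. Those given for medians come from ranked members or cells, and none covers variation between cultures. After filtering, 10684 cells remained with a median of 16504.5 RNA UMIs and 51 antibody-tag UMIs.

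The culture held cardiomyocytes and non-cardiomyocytes in nearly equal numbers. Cardiomyocyte-like clusters made up 46.8% of cells (5000) and carried TNNT2, encoding cardiac troponin T, at 6930 CPM against 338 CPM in the 5324 non-cardiomyocyte cells. Most cardiomyocyte-like cells expressed SHOX2. This gene, a transcription factor of the sinus node on chromosome 3 at 158095905 to 158106420, was detected in 89.5% of them (88.6 to 90.3%) after thinning and 97% unthinned, against 6.18% of non-cardiomyocytes, at median depths of 16095 and 17566.5 UMIs. Clusters 2, 8 and 9, with 2272 cells, were named pacemaker-like and carried TBX3, a repressor of the working myocardial programme, at 324 CPM. Cluster 18, with 186 cells, was named working-like and carried the working gene NKX2-5 at 311 CPM against 8.04 CPM in pacemaker-like cells, though it also had SHOX2 at 435 CPM and TBX3 at 151 CPM. Clusters 4 and 6, with 1510 cells, had SHOX2 at 655 and 528 CPM but TBX3 at 26.7 and 58.8 CPM, and were kept apart as other cardiomyocyte-like cells. A further 1032 cardiomyocyte-like cells in clusters 10, 15 and 16 were cycling. Among the other cells, 583 were fibroblast or mesenchymal-like, with COL1A1 at 6518 CPM, 406 were epicardial-like and 4335 stayed unnamed, while 360 cells in clusters 17 and 19 were too shallow to name. No cluster was endothelial or blood-like, and over all kept cells PECAM1 gave 23 counts, CDH5 gave 19 and PTPRC gave 2. Clusters 8 and 9 held TBX3 beside the ventricular marker MYL3 among their leading genes against other cardiomyocyte-like clusters. Against all clusters they held MYL3 and no pacemaker marker, so values are also given by cluster number.

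CD34 protein was concentrated in the clusters named pacemaker-like, by a rule set after the CD34 level of each cluster had been seen. Their median was 179 antibody-tag UMIs (quartiles 71 and 520), against 45.5 (31 and 71.25) in working-like cells, 53 (37 and 82) in other cardiomyocyte-like cells and 41 (30 and 58) in all non-cardiomyocytes. The pacemaker-like median was 4.37 times the non-cardiomyocyte median, and 2.79 times at the lower clustering resolution and 2.80 times with the stricter cell filter. The background level of 163 antibody-tag UMIs was passed by 52.8% of pacemaker-like cells (50.7 to 54.9%). It was passed by 5.91% of working-like cells (2.99 to 10.3%), 10.1% of other cardiomyocyte-like cells (8.59 to 11.7%) and 2.74% of non-cardiomyocytes (2.32 to 3.22%). The last share was largely set in advance, because most non-cardiomyocytes are the 4335 unnamed cells that define the level, of which 1.01% passed it. Cycling cardiomyocyte-like cells lay between, with a median of 87.5 and 35.7% over the background level (32.7 to 38.7%). The level that marks the highest 25% of all cells was reached by 66.3% of pacemaker-like cells (64.3 to 68.2%) and 14.0% of working-like cells (9.34 to 19.8%). By cluster, the medians were 165.5 in cluster 2, 131 in cluster 8 and 283 in cluster 9, while clusters 4 and 6, which also expressed SHOX2, had medians of 52 and 53. Within every pacemaker-like cluster the distribution was wide, and the lower quartile of cluster 8 was 56.

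**Figure D1:**
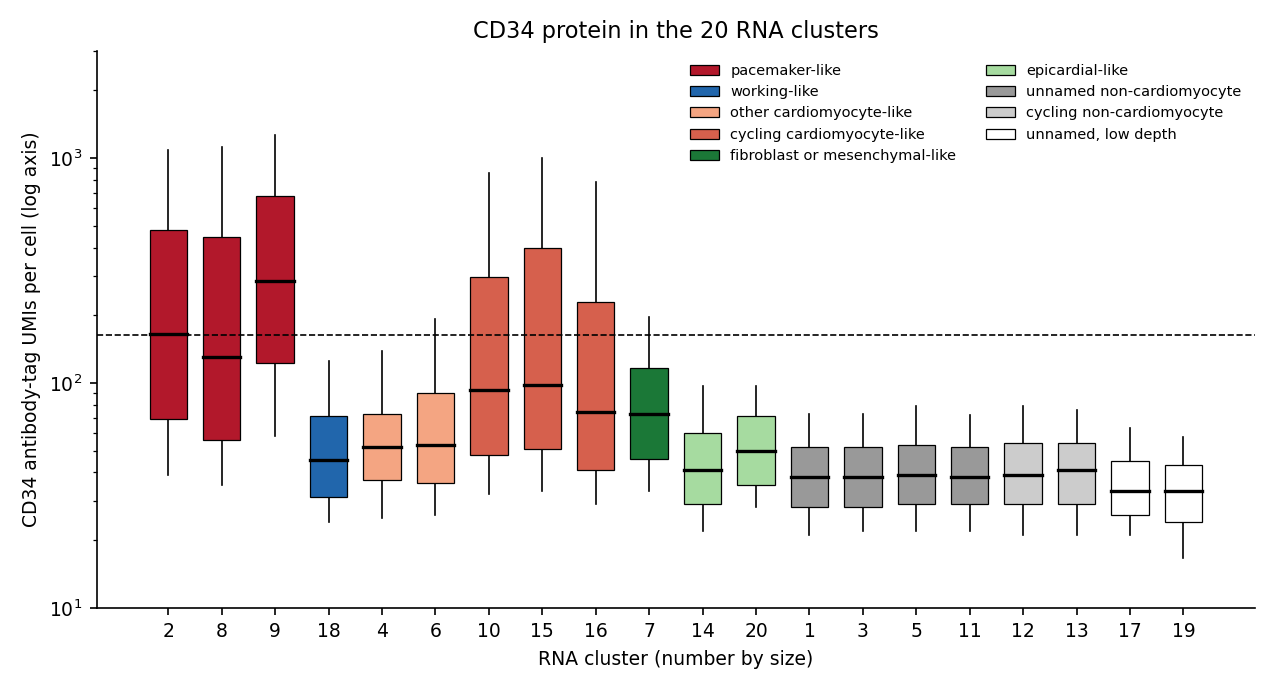
CD34 protein as antibody-tag UMIs per cell (log axis) in each cluster, with boxes from the lower to the upper quartile, a line at the median, whiskers from the 10th to the 90th percentile and a dashed line at the background level of 163. Clusters 2, 8 and 9 have medians of 165.5, 131 and 283, whereas clusters 4 and 6 have medians of 52 and 53.

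Cells with the most CD34 protein were mainly cardiomyocytes, and mainly of the pacemaker-like clusters. Groups were the cells with the highest and lowest 25% of antibody-tag UMIs. Among the 2691 CD34-high cells (100 or more), 85.1% were cardiomyocyte-like (83.7 to 86.4%), against 24.2% (22.6 to 25.8%) of the 2831 CD34-low cells (34 or fewer). Pacemaker-like cells made up 56.0% of CD34-high cells (54.1 to 57.9%) and 5.37% of CD34-low cells (4.57 to 6.26%). By number, clusters 2, 8 and 9 held 28.2%, 12.6% and 15.1% of CD34-high cells and 2.93%, 1.84% and 0.60% of CD34-low cells. Clusters that the naming rule kept out of the class were also present. Cycling cardiomyocyte-like cells made up 17.7% of CD34-high and 5.19% of CD34-low cells, other cardiomyocyte-like cells 10.5% and 11.4%, and fibroblast-like cells 6.99% and 2.15%. Among cardiomyocyte-like cells alone, pacemaker-like cells were 71.8% (69.3 to 74.3%) of the 1250 CD34-high cells (280 or more) and 24.0% (21.7 to 26.4%) of the 1284 CD34-low cells (46 or fewer). Working-like cells were 0.560% and 7.48% of the same groups. These shares depended on how clusters were drawn and named. Among CD34-high cells of all kinds the pacemaker-like share went from 25.3% with a stricter cell filter to 64.0% at the lower clustering resolution, and among CD34-low cells it was 4.28% and 12.4%. Among cardiomyocyte-like cells the CD34-high and CD34-low shares were 31.1% and 23.1% with the stricter filter and 77.0% and 52.3% at the lower resolution. With the stricter filter, clusters led by MYL3 and by EMC10, with leading genes like those of clusters 9 and 8, were named other cardiomyocyte-like. Their pacemaker scores of 0.295 and 0.236 exceeded the 0.161 of the only pacemaker-like cluster. They missed the name because no pacemaker marker was among their leading 10 genes against other cardiomyocyte-like clusters.

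CD34 protein and CD34 transcript went together in cardiomyocytes. CD34 (ENSG00000174059), on GRCh38 chromosome 1 at 207880972 to 207911125, had 24.5 CPM (22.5 to 26.6) in CD34-high cardiomyocyte-like cells and 0.561 CPM (0.28 to 1.0) in CD34-low ones, a 43.6-fold difference (24.2 to 87.8). Within pacemaker-like cells the levels were 34.6 and 0.973 CPM, a 35.6-fold difference (17.8 to 83.1), and a CD34 UMI was found in 15% and 0.361% of them thinned and 35.9% and 1.23% unthinned, with 3 and 16 left out and median depths of 15973 and 14029.5. The transcript was rare even so. After thinning, 10.5% of CD34-high cardiomyocyte-like cells (8.88 to 12.4%) had a CD34 UMI and 0.163% of CD34-low cells (0.0197 to 0.586%), with 6 and 54 cells left out. Unthinned shares were 29.0% and 0.701%, at median depths of 16456.5 and 15121 UMIs. In non-cardiomyocytes, with a median depth of 17566.5, the shares were 0.117% thinned and 0.376% unthinned, close to those of CD34-low cells. Over all kept cells the thinned shares were 5.48% in CD34-high cells (4.65 to 6.41%) and 0.121% in CD34-low cells (0.0250 to 0.354%), and the unthinned shares were 15.7% and 0.283%, with 27 and 356 cells left out and median depths of 16726 and 14876. The 444 cardiomyocyte-like cells with a CD34 UMI had a median of 811 antibody-tag UMIs, and 90.8% of them (87.7 to 93.3%) lay over the background level. Across cells, Spearman's rho between protein and transcript was 0.374 in cardiomyocyte-like cells, 0.406 in pacemaker-like cells and 0.000267 in non-cardiomyocytes, as a description with cells that are not independent replicates.

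Among cardiomyocyte-like cells, those with high CD34 protein carried far more TBX3 and less of several working myocardial genes, while SHOX2 was nearly equal. TBX3, on chromosome 12 at 114670255 to 114684175, had the highest ratio among genes at 50 CPM or more, CD34 aside, at 398 CPM in CD34-high and 70.4 CPM in CD34-low cells (5.66-fold, 5.34 to 5.99). SHOX2 was the same in both at 569 and 567 CPM (1.0-fold, 0.979 to 1.03). Other higher genes were NECAB1, a neuronal calcium-binding protein (5.10-fold), ALDH1A1, which makes retinoic acid (3.90-fold), and HAMP, which encodes the iron regulator hepcidin (3.36-fold). CAPN3, encoding a muscle calpain, was 3.06-fold higher, MYH11, a smooth muscle myosin, 3.0-fold, GNAO1, a G protein subunit, 2.63-fold, and KCNJ5, a subunit of the acetylcholine-gated potassium channel, 2.58-fold. The metallothioneins MT1E, MT2A, MT1X and MT1G, which bind zinc and copper, were 3.50-, 3.01-, 2.71- and 2.61-fold higher. Lower genes included matrix and cytoskeleton genes. MGP, matrix Gla protein, had a ratio of 0.133 (0.121 to 0.146), COL1A2 of 0.228, COL1A1 of 0.248, SERPINF1 of 0.246 and the thymosin gene TMSB4X of 0.276. The remaining lower genes were AL136171.2 (0.247), the calcineurin regulator RCAN2 (0.257), ZNF503 (0.266), the interferon-induced BST2 (0.275), SERPINI1 (0.299), the retinoic acid-binding CRABP2 (0.320) and the protocadherin PCDH7 (0.321).

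The CD34-high and CD34-low groups held different clusters, and many of these genes also led a cluster. All of the 12 higher genes led pacemaker-like clusters, as did BMP4 and MYL3. MGP, COL1A1, COL1A2, TMSB4X, SERPINF1, RCAN2 and AL136171.2 led cluster 4, and SERPINI1 and TNNI3 led cluster 6. Ratios were therefore also taken with groups drawn inside each cluster, an alternative added after the data were seen. TBX3 then had a 2.97-fold higher level (2.82 to 3.12) and NECAB1 2.84-fold, the highest of the 12. The others ran from 2.13-fold for CAPN3 to 1.44-fold for MT1G, with ALDH1A1 at 2.05-fold, HAMP at 1.90-fold, MT1E at 1.86-fold and MYH11 at 1.62-fold. NKX2-5 had a ratio of 0.591 (0.523 to 0.667). MGP instead had a ratio of 1.18 and COL1A2 of 1.03, though both were lower over all cardiomyocyte-like cells. There the CD34-low group drew 25.1% of its cells from cluster 4, which these genes led, and the CD34-high group 2.32%. The other named lower genes stayed lower within clusters but were less far apart, from 0.529 for AL136171.2 to 0.886 for COL1A1. Between these, RCAN2 had a ratio of 0.583, TMSB4X of 0.731, CRABP2 of 0.795 and SERPINF1 of 0.828.

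Of the 12 pacemaker genes, 10 were measured, and 6 were higher, none lower and 4 between, with a median log2 ratio of 0.39 at percentile 100 of matched lists, against 0.02 over all 3219 measured genes. Members named in this and the following groups were picked after their values were seen. The higher members after TBX3 were BMP4 (2.19-fold), the calcium sensor VSNL1 (1.54-fold), CPNE5 (1.44-fold), the calcium channel gene CACNA1D (1.33-fold) and the sinus node transcription factor TBX18 (1.28-fold). HCN4, encoding a channel of the pacemaker current, had a ratio of 1.18, and ISL1, a transcription factor of sinus node progenitors, 1.11, which turned to a log2 ratio of -0.017 per RNA UMI. TBX3 and BMP4 also took part in naming the pacemaker-like clusters, though the groups compared here were drawn over all cardiomyocyte-like cells. The 4 pacemaker transcription factors had a median log2 ratio of 0.26 (2 higher, none lower; percentile 99.3). Within clusters the pacemaker gene median was 0.11 (percentile 99.7), with 3 higher and none lower. Its interval over members was -0.081 to 0.465, which includes 0. The median of the transcription factors was 0.043 within clusters (percentile 72.7), with 1 higher. BMP4 was then 1.38-fold and VSNL1 1.32-fold higher, while TBX18 had a ratio of 1.07 and ISL1 of 0.918 (0.854 to 0.987). At a floor of 10 CPM, 1 pacemaker gene was lower, RGS6 at 0.675 (0.611 to 0.746).

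Most working cardiomyocyte genes lay under the floor of 50 CPM. Of 12, 3 were measured, NPPA, ADM and PAM, with 1 higher and 2 between and a median log2 ratio of -0.10 (percentile 11.6). At a floor of 10 CPM, 10 were measured, 6 of them lower and 2 higher, and the median was -1.12 (percentile 0). NKX2-5, the homeobox gene of working myocardium, had 6.07 against 45.0 CPM (ratio 0.135, 0.112 to 0.162). Ratios were 0.219 for GJA5, encoding a fast-conducting connexin, 0.262 for the potassium channel gene KCNA5, 0.122 for GJA1 on 20 against 144 counts and 0.0881 for sarcolipin, SLN. The atrial peptide gene NPPA did not follow them, at 451 against 485 CPM (0.931, 0.905 to 0.957). Its direction was not stable, with a log2 ratio of 0.11 per RNA UMI. After thinning, an NPPA UMI was found in 55.1% of CD34-high and 39.2% of CD34-low cells, 77.4% and 56.4% unthinned, against 5.77% and 17.2% of non-cardiomyocytes. After thinning, an NKX2-5 UMI was found in 2.17% of CD34-high (1.44 to 3.14%) and 14.4% of CD34-low cells (12.5 to 16.5%), 4.96% and 22.4% unthinned, against 0.195% and 0.826% of non-cardiomyocytes. A TBX3 UMI was found in 70.4% (67.8 to 72.9%) and 24.6% (22.2 to 27.1%), 90.5% and 46.0% unthinned, against 29.5% and 60.0% of non-cardiomyocytes. The same cells were left out as for CD34, and 191 of the non-cardiomyocytes, at the same median depths.

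**Figure D2:**
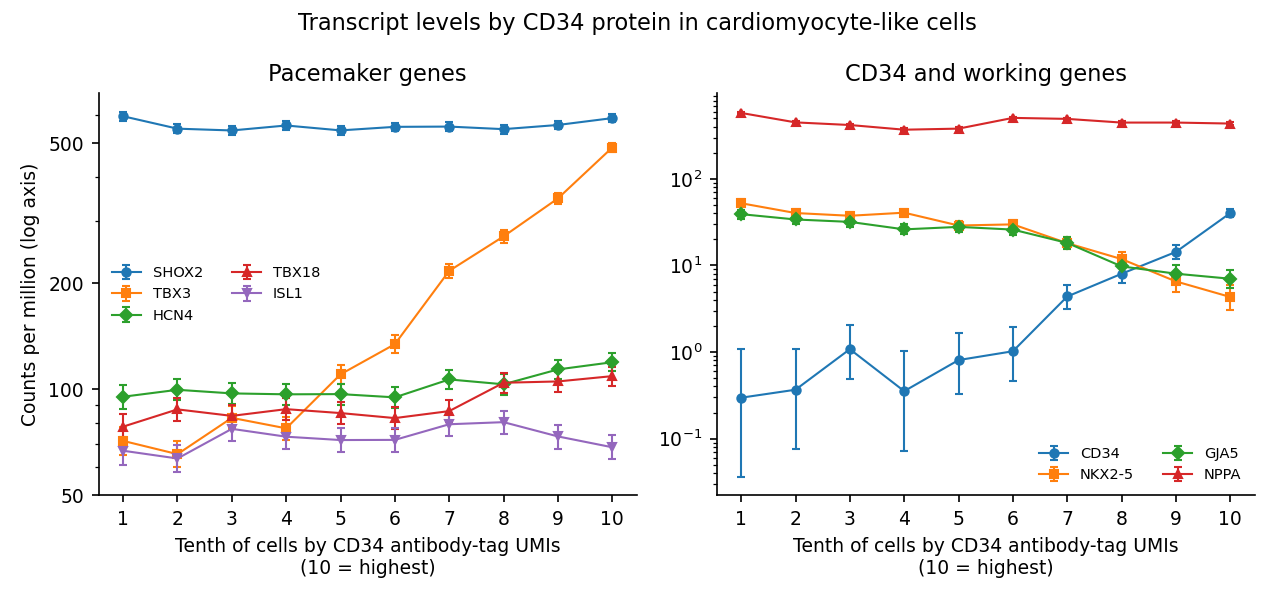
Transcript levels in CPM (log axes) of pacemaker genes (left) and of CD34 and working genes (right) across 10 equal groups of 500 cardiomyocyte-like cells ordered by CD34 antibody-tag UMIs, with exact Poisson 95% intervals as bars. From the lowest to the highest group TBX3 goes from 71.4 to 486 CPM and NKX2-5 from 52.4 to 4.33 CPM, while SHOX2 is 597 and 590 CPM.

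Genes of the contractile programme went both ways. All 13 sarcomere genes were measured, with a median log2 ratio of 0.01 (percentile 25.8), 3 higher, 1 lower and 9 between, and within clusters none was higher and 1 lower. The atrial light chains and troponin C were somewhat higher, MYL4 1.35-fold, MYL7 1.3-fold and TNNC1 1.28-fold, whereas adult cardiac troponin I, TNNI3, had a ratio of 0.414 (0.402 to 0.426). Of 8 ventricular genes 3 were measured, with a median log2 ratio of 0.40 (percentile 99.7). They were the light chain MYL3 (2.17-fold, 2.11 to 2.24), the creatine kinase CKM (1.32-fold) and FHL2 (1.18-fold), while MYH7 had 3.06 against 8.83 CPM and MYL2 5 against 0 counts. Ion channel and gap junction genes had a median of 0.07 (7 measured, 2 higher, 1 lower; percentile 80.4), with KCNJ5 higher and its partner KCNJ3 at 0.716. Calcium handling genes had a median of -0.03 (7 measured, none higher, 2 lower; percentile 13.5), with the ryanodine receptor gene RYR2 at 0.764, and within clusters none was lower. Oxidative phosphorylation and glycolysis genes stayed between the limits in every measured member, with medians of -0.04 (14 members, percentile 3.81) and 0.05 (11 members, percentile 65.7).

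Among signalling and other groups, BMP response genes had a median log2 ratio of 0.06 (8 measured, 2 higher, none lower; percentile 72.6), the higher ones being ID1 (1.72-fold, 1.66 to 1.78) and BAMBI (1.35-fold). Retinoic acid response genes had a median of -0.04 over 3 members (percentile 23.3), NR2F1 at 1.3-fold, NR2F2 at 0.971 and CRABP2 at 0.320. Proliferation genes had a median of 0.12 (8 measured, 2 higher, none lower; percentile 96.7), TOP2A at 1.28-fold and UBE2C at 1.33-fold, and -0.27 when protein was scaled per RNA UMI. Stress and immediate early genes had a median of -0.27 (7 measured, none higher, 3 lower; percentile 0.695), with ATF3 at 0.580 and EGR1 at 0.683, and within clusters the median was -0.15 with none lower of 5 measured. Fibroblast genes had a median of -1.43 (5 measured, 1 higher, 4 lower; percentile 0), with COL3A1 at 0.370 and PDGFRA at 1.45, and this median was 0.26 with called doublets kept and -0.07 within clusters. Fewer than 3 members were measured of the atrioventricular, WNT, Notch, endothelial, epicardial, sialomucin and surface protein groups. In these, TGFB2 had a ratio of 0.587, BMP2 of 1.61 and the neural adhesion gene NCAM1 of 0.724. The CD34 relatives PODXL and PODXL2 had ratios of 0.906 (0.689 to 1.19) and 1.0 (0.677 to 1.48). The endothelial gene CLDN5 gave 83 counts in CD34-high cells, 80 of them in 1 cell, and is not read as a difference.

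Within pacemaker-like cells alone, high CD34 protein also went with TBX3. TBX3 had 516 CPM in the 569 CD34-high cells (520 antibody-tag UMIs or more) and 161 CPM in the 570 CD34-low cells (71 or fewer), a 3.21-fold difference (3.02 to 3.42), while SHOX2 had 610 and 589 CPM (1.04-fold, 0.998 to 1.08). MYL3, an essential light chain of ventricular and slow muscle, was 2.83-fold higher (2.71 to 2.97), LRRTM3, a neuronal adhesion gene, 2.96-fold, NECAB1 2.78-fold, CAPN3 2.71-fold and GNAO1 2.21-fold. MT1G, MT1E, MT1X and MT2A were 2.87-, 2.35-, 2.32- and 2.17-fold higher, the DNA sensor IFI16 2.16-fold and PAM, which amidates peptides, 2.14-fold. Lower genes were AL136171.2 (0.253), SERPINI1 (0.285), PRKG1-AS1 (0.306), the angiopoietin gene ANGPT1 (0.375), the WNT antagonist SFRP5 (0.413) and TNNI3 (0.435, 0.415 to 0.457). They were followed by A2M (0.452), the protease gene HTRA1 (0.487), TMSB4X (0.487), the matrix gene VCAN (0.494), vimentin, VIM (0.496), and COL3A1 (0.497). LRRTM3 also led cluster 9, SFRP5 cluster 2, A2M cluster 4, and PRKG1-AS1, HTRA1, SERPINI1 and TNNI3 cluster 6.

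The pacemaker gene group had a slightly higher median within this class, with an interval over its members of -0.057 to 0.55 that includes 0. The group had a median log2 ratio of 0.15 (10 measured, 4 higher, none lower, 6 between; percentile 99.96), and after TBX3 the higher members were VSNL1 (1.47-fold), CPNE5 (1.40-fold) and BMP4 (1.35-fold). At a floor of 10 CPM the median was 0.093 over 11 measured, with 1 lower, RGS6 at 0.761 (0.650 to 0.892). HCN4 had a ratio of 1.15 (1.06 to 1.26), TBX18 of 1.04 and ISL1 of 0.863 (0.772 to 0.964), and the pacemaker transcription factors had a median of 0.05 (4 measured, 1 higher; percentile 77.4). Working genes at 50 CPM or more had a median of 0.36 (3 measured, 2 higher, none lower; percentile 99.6) from PAM, NPPA (1.28-fold) and ADM, and at a floor of 10 CPM a median of -0.40 (9 measured, 2 higher, 5 lower; percentile 0.0100). NKX2-5 had 33 against 88 counts (ratio 0.324, 0.210 to 0.488), which turned to a log2 ratio of 1.19 (-0.37 to 3.01) in cluster 2 alone. GJA5 had a ratio of 0.301, which turned to a log2 ratio of 0.060 with called doublets kept. Ventricular genes had a median of 0.30 (3 measured, 1 higher; percentile 99.3), sarcomere genes of 0.03 (13 measured, 2 higher, 1 lower; percentile 68.4), ion channel genes of 0.09 (7 measured, 2 higher; percentile 93.4) with KCNJ5 at 2.01-fold and KCNJ3 at 1.3-fold, and calcium handling genes of -0.04 (7 measured, 1 higher; percentile 10.6). BMP response genes had a median of 0.07 (7 measured, 1 higher; percentile 91.8) with ID1 at 1.64-fold, and oxidative phosphorylation genes of -0.09 (14 measured, 1 lower; percentile 0.260). Glycolysis genes had -0.04 (11 measured, all between; percentile 8.08), fibroblast genes -0.46 (3 measured, 1 higher, 2 lower; percentile 0.430) and stress genes -0.23 (5 measured, 1 lower; percentile 0.275). The stress median was -0.15 within clusters, with none lower, and ran from -0.49 to 0.0053 over the alternatives. Proliferation and retinoic acid response genes also had fewer than 3 measured members in this class. At a floor of 10 CPM proliferation genes had a median of -0.54 (5 measured, none higher, 3 lower; percentile 0.495), against 0.16 in cardiomyocyte-like cells, and atrioventricular genes -0.63 (4 measured, none higher, 3 lower; percentile 0.0100). Clusters 2, 8 and 9 made up 47.8%, 23.2% and 29.0% of the CD34-high and 54.9%, 32.8% and 12.3% of the CD34-low cells. With groups drawn inside each cluster TBX3 was 2.77-fold (2.61 to 2.93) and MYL3 1.88-fold higher (1.81 to 1.96). The metallothioneins, which led cluster 9, were less far apart there, MT1E at 1.75-fold, MT1G and MT1X at 1.65-fold and MT2A at 1.51-fold.

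**Figure D3:**
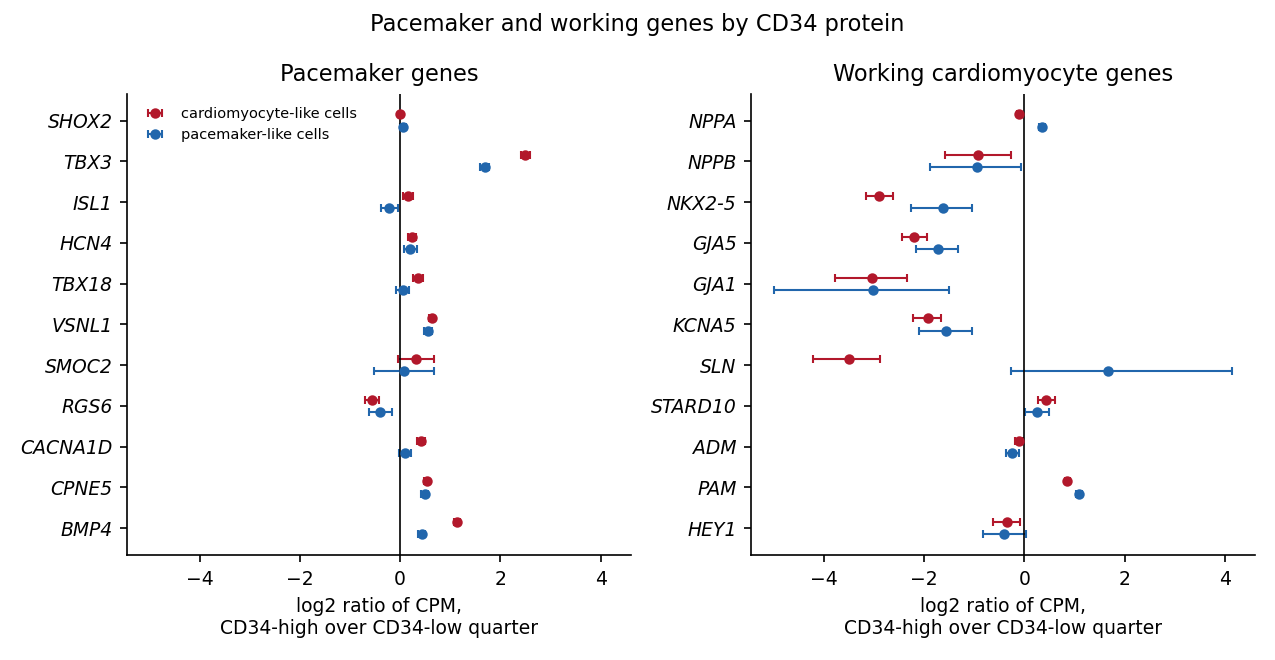
Log2 ratio of CPM in CD34-high over CD34-low cells for pacemaker genes (left) and working cardiomyocyte genes (right), in cardiomyocyte-like cells (red) and in pacemaker-like cells (blue), with bars for exact 95% counting intervals. TBX3 lies at 2.5 and 1.68, SHOX2 at 0.0058 and 0.052 and NKX2-5 at -2.89 and -1.63, and SLN in pacemaker-like cells rests on 11 against 3 counts.

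Taken gene by gene over all cardiomyocyte-like clusters, whatever their further name, CD34 protein went with TBX3 more than with SHOX2, ISL1, HCN4 or TBX18, the other pacemaker genes taken this way. The 2131 cells with a TBX3 UMI after thinning had a median of 197 antibody-tag UMIs, and the 2775 without had 61, a ratio of 3.23, with 55.2% (53.0 to 57.3%) and 19.6% (18.1 to 21.1%) over the background level. For SHOX2 the medians were 89 and 71, with 35.7% (34.3 to 37.2%) and 29.2% (25.3 to 33.3%) over background. ISL1, HCN4 and TBX18 had medians of 94 and 84, 94 and 83, and 95.5 and 83.5, and the ISL1 ratio of 1.12 turned to 0.943 at the lower thinning depth. Cells with an NKX2-5 UMI had a lower median than those without, 51 against 94, and 10.8% (7.93 to 14.3%) against 37.2% (35.8 to 38.6%) lay over background. Cells with an NPPA UMI had a higher median, 116.5 against 73. Thinning left out 94 cells. TBX3 was detected in 43.4% of cardiomyocyte-like cells (64.8% unthinned) and NKX2-5 in 8.11% (14.4% unthinned), at the median depths given for SHOX2 and beside the shares of non-cardiomyocytes given above.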

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

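Among the tests below, those on RNA depth, on antibody binding and on the sampling of a rare transcript were chosen after the result was seen. No biological explanation was tested, since the series holds 1 culture and no group to set against it.

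CD34 protein was also measured in barcodes that the comparisons left out, which hold data outside the main measurement. Over the background level lay 1.77% (1.24 to 2.46%) of the 1975 barcodes with too few genes, 16.2% (13.6 to 19.1%) of the 735 barcodes with enough genes but over the mitochondrial limit, and 36.5% (34 to 39.1%) of the 1435 called doublets. The level was passed by 17.6% of all kept cells and by 2.74% of non-cardiomyocytes, most of which set that level. Barcodes over the mitochondrial limit lay near the share of all kept cells. Called doublets lay above it, at a median depth of 30877 RNA UMIs against 16504.5 in kept cells. In the left-out groups, in the same order, TNNT2 was at 3073, 2461 and 3091 CPM, against 3368 CPM in all kept cells. CD34 transcript in these groups was 2.41, 3.18 and 3.34 CPM.

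Genes higher in CD34-high cardiomyocyte-like cells were weighed as a first pattern. With groups drawn inside each cluster, the median log2 ratio of the 12 named higher genes was 0.86 against 1.6 over all cardiomyocyte-like cells, with the lowest of the 12 at 0.52. For these genes, which were chosen for their high ratios, each kept between 0.377 and 0.675 of its log2 ratio, but such groups also differ less in CD34 protein, so how far the mix of clusters contributes stays open. With groups drawn inside 10 bins of mitochondrial share the median was 1.63, and inside 10 bins of RNA UMIs it was 1.73, which argues against both as the source. A continuous difference between cells that clusters do not capture stays open as a hypothesis.

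CD34 protein in fibroblast-like cells was the second pattern. Their median of 73 antibody-tag UMIs was 1.87 times that of other non-cardiomyocytes. RNA depth is argued against as the source of the raised median, because the ratio per RNA UMI was 1.94. Cardiomyocyte doublets left in the cluster are argued against for the fibroblast-like cells over the background level. Those cells exceeded the others in 5 abundant cardiomyocyte transcripts by a median of only 1.38% of the cardiomyocyte level (1.3 to 2.7%). In the 74 such cells between the background level and their 90th percentile, CD34 transcript was 0.645 CPM on 1 count, with an upper limit of 3.60 CPM, against a lower limit of 11.6 CPM in 1454 cardiomyocyte-like cells of the same range, whose limit was set after an extreme barcode was seen. Antibody binding without CD34 transcript may therefore account for the signal of these fibroblast-like cells, though the medians of 237 and 384.5 antibody-tag UMIs differed and long-lived protein was not tested. Neither this test nor that on doublets covers the raised median of 73, which lies under the background level. CD34 transcript was 0.478 CPM (0.155 to 1.12) in all fibroblast-like cells. In the 500 cardiomyocyte-like cells of the tenth with a median of 73 it was 0.808 CPM (0.325 to 1.66), an overlapping interval.

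The lack of a CD34 UMI in most CD34-high cardiomyocyte-like cells was the third pattern. A CD34 UMI was found in 29.0% of the 1250 cells, 0.841 of the 34.4% that Poisson sampling of 1 common level gives at their depths. The level was not common to all of them, at 14.4 CPM (11.9 to 17.1) in the 500 cardiomyocyte-like cells ranked next below the highest 500 by CD34 protein and 40.3 CPM (36.4 to 44.7) in the highest 500. Sampling of a rare transcript may account for many cells without one, and how much of the shortfall comes from this difference in level was not tested.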

How the results depend on the processing

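Some alternatives, named here as added, were chosen after the data were seen, and no cause was tested unless stated. No paired analysis was possible because the series holds 1 culture. All 6 main comparisons kept their direction in every alternative that gave a value, though some of their intervals included no difference. The ratio of pacemaker-like to non-cardiomyocyte CD34 protein (4.37) was 2.80 with the stricter cell filter, 2.79 and 5.23 at the lower and higher clustering resolution, 5.18 per RNA UMI and 4.04 with the pacemaker-like class narrowed to cluster 2 (added). The ratio of pacemaker-like to working-like CD34 protein (3.93) ran from 2.54 to 4.28. At the higher resolution the working-like class held 1055 cells, among them a cluster of 287 led by SFRP5 and MYLK, which led pacemaker-like cluster 2 in the main run. The pacemaker-like share of the CD34-high group (56.0%) was 34.6% with doublets kept, 25.3% with the stricter filter, 64.0% and 46.6% at the lower and higher resolution and 52.6% per RNA UMI. It was 69.4% in the highest 10%, 36.2% above the median, 53.3% within bins of RNA UMIs and 28.2% with the narrowed class (added), which leaves out 581 and 513 cells. The CD34-low share (5.37%) ran from 2.93% to 12.4%, and in cardiomyocyte-like cells the shares (71.8% and 24.0%) ran from 31.1% to 77.0% and from 13.7% to 52.3%. The thinned share with a CD34 UMI (5.48%) was 6.62% per RNA UMI, 11.4% in the highest 10%, 3.0% above the median and 3.42% at the lower thinning depth, where fewer UMIs are kept. The pacemaker gene medians (0.39 and 0.15) and the SHOX2 detection ratio (1.3) had intervals of 0.013 to 1.13, -0.057 to 0.55 and 1.06 to 1.43. They stayed within these, over 0.11 to 0.45, 0.09 to 0.25 and 1.1 to 1.3. The interval of the pacemaker gene median in cardiomyocyte-like cells included 0 with doublets kept (-0.110 to 0.970) and for the highest and lowest 10% (-0.019 to 1.32). It also included 0 within clusters (-0.081 to 0.465, added). The interval of the SHOX2 ratio included 1 with doublets kept (0.978 to 1.28), the stricter filter (0.889 to 1.38) and the lower thinning depth (0.943 to 1.26). Log2 ratios whose interval excluded 0 and that changed sign were GJA5 at 0.060 in pacemaker-like cells with doublets kept, and, in cardiomyocyte-like cells, ISL1 at -0.017 and NPPA at 0.11 per RNA UMI and NPPA at 0.10 for the split at the median. Among added alternatives they were NKX2-5 at 1.19 in the narrowed class, NPPA at 0.051 for the split at the background level, and MGP at 0.24, COL1A2 at 0.042, ISL1 at -0.12 and NPPA at 0.0012 within clusters. SHOX2, whose main intervals include 0, ran from -0.11 to 0.052 in cardiomyocyte-like and from -0.014 to 0.12 in pacemaker-like cells. Within bins of RNA UMIs its ratio in pacemaker-like cells was 1.04 (1.003 to 1.083), an interval that excludes 1. The ISL1 detection ratio (1.12) was 0.943 at the lower thinning depth. For the 48 results of the rule for named genes, 574 of 576 alternative values over 13 settings kept their direction, the exceptions being MGP and COL1A2 within clusters. These genes were picked for extreme ratios in largely the same cells, so a kept direction was likely in advance. Leaving out cycling clusters gave no value for the pacemaker-like class, which holds none. Counts of the CD34 transcript are few, with 11 in CD34-low cardiomyocyte-like cells and 8 in CD34-low pacemaker-like cells.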

Other observations

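The values here were singled out after the data were seen. Outside the cardiomyocytes, cells with and without TBX3 had similarly low CD34 protein. CD34 transcript was only 0.213 CPM there and most of these cells set the background level, so a tie could hardly have shown. The 1542 non-cardiomyocyte cells with a TBX3 UMI after thinning had a median of 40 antibody-tag UMIs (quartiles 29 and 58) and the 3591 without had 42 (31 and 58.5), with 2.79% (2.03 to 3.74%) and 2.78% (2.27 to 3.38%) over the background level and 191 cells left out. TBX3 reached 107 CPM in the unnamed cluster 1, led by GRIA4 and the tight junction gene CLDN3, where the median was 38 antibody-tag UMIs and CD34 transcript 0.290 CPM.

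Cells with endothelial genes were rare. With at least 3 of 10 endothelial genes detected there were 7 cells, spread over the epicardial-like, fibroblast-like and other cardiomyocyte-like clusters. They had a median of 127 antibody-tag UMIs, 3 of them over the background level, and 0 CD34 UMIs. The cells with 7 or more of the genes had 300, 869, 127 and 719 antibody-tag UMIs. Those with only 3, all fibroblast-like, had 55, 26 and 36. These are too few cells to set a CD34 level. The fibroblast-like cluster also held 1 barcode with 401428 antibody-tag UMIs and 0 CD34 UMIs at 14017 RNA UMIs, 18.3% of all antibody-tag UMIs of kept cells, whereas the highest cardiomyocyte-like cell had 7294. Medians and groups by rank are little affected by a single barcode.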
